A study of Homo sapiens with 22 samples.

How the data were processed

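Chromatin accessibility was measured in single nuclei of H9 cells, an established human pluripotent stem cell line, by droplet-based snATAC-seq. In this assay the transposase Tn5 inserts adapters into open DNA, and a barcode assigns each insertion to a nucleus. Per the labels' protocols, Tn5 carried a barcode of its own, and dead cells were removed by sorting for DAPI-negative cells. The cells were differentiated towards cardiomyocytes by a 2D and by a 3D protocol. The labels name 22 libraries in 11 groups of 2, namely undifferentiated cells at D0, the 2D format at D2, D5, D7, D15 and D25, and the 3D format at D3, D5, D7, D15 and D25. They do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

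The deposited matrix held whole counts for 421166 peaks in 216245 nuclei, with 485382404 entries above 0, per the file headers. It was not normalised. Per the submitters' processing notes, the build hg38, BWA and ArchR were used, with no version. Filters on nuclei and peaks, the peak caller and any removal of doublets are not given in the sources used here. Every entry was between 1 and 4, and 65.0% of entries were 2 against 31.6% that were 1, so both ends of a fragment appear to have been counted up to a ceiling of 4. This is a reading of the values, and an alternative with fragments in place of ends was run. The ceiling can understate accessibility where a nucleus had more insertions, and how the peak set was built from the libraries is not given in the sources used here.

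Each peak carried a running number that started again at 1 in each of 23 blocks, and the list used here paired no peak with a chromosome, a position or a gene. Peaks were therefore followed as sets and by block and number. The comparisons planned for gene loci, gene lists, consensus motifs and nuclei named by marker genes were not run, and clusters of nuclei kept numbers in place of names. The alternatives planned for those comparisons were not run either. Blocks are not equated with chromosomes here.

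The matrix listed 24 library names, since the D0 nuclei appeared under the names of both formats. The copies of D0 replicate 2 were identical in all 11056 nuclei. Those of D0 replicate 1 shared 7957 of 8635 barcodes, identical in each, and 678 barcodes stood in only 1 of them. One copy of each was used, which left 2 names and 19691 nuclei not used here and 196554 nuclei in the comparisons. The names with a D2 library were taken as the 2D format and those with a D3 library as the 3D format, as the labels list those days. Barcodes had 20 bases in D0 replicate 1 and 3D D3 replicate 1 and 22 in the others.

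Counts were summed over the nuclei of each library and tested with edgeR 4.0.16 (with limma 3.58.1, in R 4.3.3), since nuclei are not replicates. Peaks were filtered with filterByExpr at a minimum count of 10, which removed 6437 peaks and left 414729. Libraries were scaled with TMM, and a quasi-likelihood F test was fitted with 1 coefficient per group over all 22 libraries, so that the 11 groups shared 1 estimate of the spread with 11 residual degrees of freedom. The common biological coefficient of variation was 0.368 and the prior degrees of freedom were 11.8. A peak was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison and a fold of at least 2. A called peak is said to have opened where it was higher on the later day and to have closed where it was lower. Levels are given as CPM, the counts scaled by effective library size. The rule for single peaks took, among called peaks of above-median level whose libraries did not overlap between the groups, the 2 with the largest rise and the 2 with the largest fall. They are given for 2D D25 against D0 only, since the numbers are not paired with genes. Where every library of a group held 0 counts, the fold is a lower bound, the mean CPM of the other group against 3 counts over the group's libraries on the same effective library sizes.

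Nuclei with at least 1000 counts (195495) were embedded by TF-IDF and a truncated SVD of the 91942 peaks with a count in at least 0.5% of nuclei. Of 30 components, 1 that followed depth was left out. A graph of 20 neighbours was clustered with leidenalg 0.10.2 and python-igraph 0.11.9 at a resolution of 0.8, which gave 15 clusters. Shares of nuclei were compared between formats with edgeR's quasi-likelihood test on nuclei per cluster. Intervals of single shares are 95% Wilson intervals and cover counting error only. No doublet caller was run. An alternative without the 5% of nuclei with the most counts in each library was run in its place. Sums, embedding and figures were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

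The peak test was tested on simulated data drawn from the means and depths of the real libraries, with 200 peaks changed per comparison. For 3D against 2D at D25 it recovered 0% of 2-fold, 14.9% of 4-fold and 43.9% of 8-fold changes and called 3 of the unchanged peaks, so a peak without a call was not shown to be unchanged. A comparison with more changed peaks has a less strict adjusted threshold, so these shares do not carry over to it. The cluster test was simulated for the same comparison at a dispersion of 0.2. It recovered 94% of 8-fold changes in share and also called 7.54% of unchanged clusters, so a called cluster may be a false call. In the real data larger estimated changes went uncalled, such as a log2 ratio of 5.73 (SE 2.82) for cluster 2 in 3D against 2D at D5. A cluster without a call was therefore not shown to be unchanged.

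The groups, the tests, the rule for single peaks and most alternatives were fixed before the data were examined. These alternatives were RLE size factors, total counts only, no filter on low counts, DESeq2 1.42.0, each nucleus counted once per peak, no nuclei with the most counts, only the groups compared in the fit, the replicate number as a block, every library thinned to the smallest total, and each library left out in turn. For clusters they were a resolution of 0.4 (12 clusters), a resolution of 1.6 (23 clusters), a minimum of 2000 counts, the block and left-out libraries. Fragments, a term for the barcode length, a scaling factor per block of peaks, and fits without cluster 9 or without clusters 9 and 15 were added after seeing the data.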

Results

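The data covered accessible chromatin in 196554 nuclei of H9 cells on the way from pluripotent cells at D0 to D25 of cardiomyocyte differentiation, in 2 culture formats. Each of the 11 groups had 2 libraries. A library held 2901 to 11253 nuclei and 5703187 to 62912600 counts in peaks. The shallowest was 2D D25 replicate 2, with a median of 1734 counts per nucleus, and the deepest 2D D2 replicate 2, with 5150. Over the tested peaks, replicates correlated at 0.914 to 0.965 in D0 and in 2D up to D15, and at 0.815 at 2D D25. In 3D the correlation was 0.919 at D3, 0.875 at D5, 0.852 at D7, 0.826 at D15 and 0.802 at D25. These are correlations across peaks, which are not independent replicates.

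The whole course was asked about first, by comparing D25 with D0 in each format. In 2D, 78572 peaks opened and 94169 closed by D25, together 41.7% of the 414729 tested. Opened peaks rose by a median log2 fold change of 2.86 and closed peaks changed by a median of -3.26. In 3D, 112115 peaks opened and 109821 closed, or 53.5%, with medians of 2.93 and -3.17. With every library thinned to the smallest total the formats lay closer together, with 118917 peaks called in 2D and 133527 in 3D. The calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 2 libraries per group). The balance of opening and closing depended on scaling. With RLE size factors the median over all peaks moved from -0.32 to -0.76 in 2D and from -0.05 to -0.56 in 3D, and the opened share of calls went from 45.5% to 32.8% (60002 opened, 122763 closed) and from 50.5% to 38.2% (85684 opened, 138541 closed). The 2D balance also turned without 2D D25 replicate 2 (73575 opened, 67361 closed), and in 3D more peaks closed than opened without any 1 of the 4 libraries.

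Single peaks went from no signal to strong signal or the reverse. Peak 7346 of block 3 had 0 counts at D0 and 33.3 ± 2.75 CPM at 2D D25 (SD, n = 2), at least 876-fold higher (adjusted p = 5.1e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It opened in steps, from 0.0953 CPM at 2D D2 to 5.01 ± 0.37 at D5, 20.2 ± 5.99 at D7 and 30.8 ± 2.98 at D15. In 3D it stood at 15.7 ± 6.54 CPM at D5 and 29.2 ± 3.83 at D25, at least 768-fold higher than at D0. Peak 21795 of block 7 also rose from 0 counts at D0, to 30.2 ± 2.9 CPM at 2D D25, at least 795-fold higher (adjusted p = 1.1e-07 in the same test). In the other direction, peak 21610 of block 3 fell from 28.3 ± 3.52 CPM at D0 to 1.12 ± 0.0173 at 2D D2 and to 0 counts at 2D D25, at least 210-fold lower (adjusted p = 2.6e-07). Peak 1587 of block 9 fell from 21.6 ± 0.746 CPM to 0 counts at 2D D25, at least 160-fold lower (adjusted p = 1.7e-05).

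The first days brought the largest step in each format among the steps between successive days. By 2D D2, 63965 peaks opened and 40185 closed against D0, with median log2 fold changes of 2.97 and -2.35. By 3D D3, 54698 opened and 35862 closed. Most early openings did not last. Of the peaks opened at 2D D2, 21.4% were also open at D25 against D0, near the 18.9% of all tested peaks, and 71.3% fell again between D2 and D25, against 25% of all. Of those closed at D2, 70.2% were also closed at D25, against 22.7% of all. In 3D, 35.4% of the peaks opened at D3 were open at D25 (27% of all) and 61.3% fell again (26.3% of all), while 79.1% of the closed ones were closed at D25 (26.5% of all). The steps compared have the D0, D2 or D3 libraries in common, so part of each share above or below that of all peaks may come from them. Both first steps counted fewer peaks when a library was left out. Leaving out any 1 of the 4 libraries gave 55733 to 66648 calls for 2D D2, against 104150 with all. For 3D D3, against 90560, there were 51313 without 3D D3 replicate 2, 49780 without D0 replicate 1 and 46008 without D0 replicate 2. With total counts as the only scaling, the opened share at 2D D2 was 52.2% in place of 61.4%.

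Called peaks followed a few courses. In 2D, 43536 peaks opened by D2 and closed again by D25, with a median log2 level over D0 of 2.94 ± 0.15 at D2 (SD of the library medians, n = 2), 1.03 ± 0.06 at D5, 0.35 ± 0.12 at D7 and -0.99 ± 0.60 at D25. Another 13706 opened by D2 and were open at D25, at 2.47 ± 0.12 and 2.66 ± 0.15. A set of 35710 opened at D5 or D7 and was open at D25, and 29156 opened after D7, rising from 0.66 ± 0.12 at D7 to 1.65 ± 0.03 at D15 and 2.39 ± 0.03 at D25. Among peaks closed at D25, 28216 were first called closed by D2, 33306 at D5 or D7 and 24911 later. These days, like those of opening, are when a peak first passed the thresholds against D0, not when its change began. The peaks first called closed at D5 or D7 already stood at -0.76 ± 0.04 at 2D D2. The later ones stood at -0.76 ± 0.11 at 2D D7. The comparisons that chose the sets above held only 2D and D0 libraries. The 3D libraries still took part through the filter, the scaling and the estimate of spread, which all 22 libraries shared. The peaks that opened and closed again in 2D stood at 2.20 ± 0.09 at 3D D3 and -0.68 ± 0.16 at 3D D25. Those opened after D7 in 2D stood at 0.84 ± 0.28 at 3D D7 and 2.52 ± 0.21 at 3D D25. A smaller set of 8275 peaks, opened at D5 or D7 in 2D and closed again by D25, stood at 2.32 ± 0.30 at 2D D7 and 1.27 ± 0.24 at 3D D7, and 18.9% of it followed the same course by the calls in 3D, against 1.53% for independent lists. The 6345 peaks chosen the same way in 3D ran the other way, at 2.15 ± 0.22 at 3D D7 and 1.75 ± 0.10 at 2D D7, so each set stood higher in the format that chose it. No test was made of differences between formats in these set levels. The D0 libraries are common to all of these levels.

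**Figure D1:**
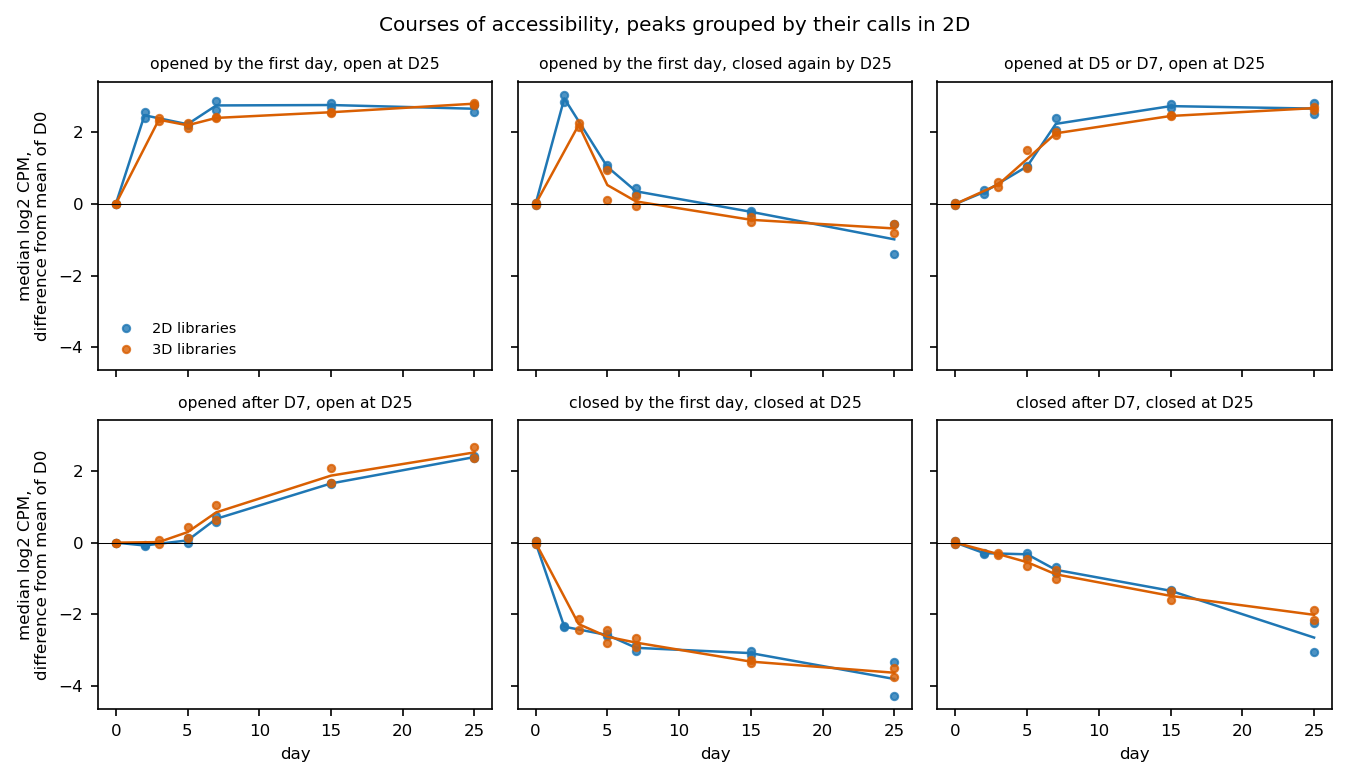
Median log2 CPM of peak sets relative to the mean of D0 (y axis) against day of differentiation (x axis), for 6 courses defined by the calls in 2D. Points are libraries, blue for 2D and orange for 3D, and lines join the group means. In the set that opened and closed again, 2D libraries peaked at 2.94 ± 0.15 at D2 and fell to -0.99 ± 0.60 at D25.

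Between later successive days the steps were smaller. From D2 to D5 in 2D, 25049 peaks opened and 39772 closed, and from D3 to D5 in 3D, 21922 opened and 29245 closed. From D5 to D7, 11051 opened and 3603 closed in 2D against 2594 and 621 in 3D. With DESeq2 the excess of opening in that step was absent in 2D, with 14884 opened and 17255 closed, and nearly absent in 3D, with 7108 and 7045. In 3D it was also absent without D5 replicate 2. From D7 to D15 the formats had 10581 opened and 8762 closed in 2D and 9927 and 8179 in 3D. From D15 to D25 only 3 peaks were called in 2D, all lower but too few to give the step a direction, and 966 in 3D, 450 higher and 516 lower. At an unadjusted p under 0.05 those last steps held 43376 and 65696 peaks, and DESeq2 called 1767 and 12506. The difference of the last step between formats was tested too, and edgeR called 0 peaks (37228 at an unadjusted p under 0.05, with no other tool run).

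These counts rested on few libraries. For 2D D5 against D2, leaving out any 1 of the 4 libraries gave 23120 to 35016 calls in place of 64821. For 2D D7 against D5 there were 1494 and 567 without 2D D5 replicate 1 or 2 and 1787 without 2D D7 replicate 2, in place of 14654. For 2D D15 against D7 the 4 left-out fits gave 2997 to 10300 in place of 19343. The 3 calls of 2D D25 against D15 became 0 without either 2D D25 library. For 3D D5 against D3 there were 21493 without 3D D3 replicate 1 and 15379 without 3D D5 replicate 2, in place of 51167. For 3D D7 against D5 there were 11 without D5 replicate 1, 5126 without D5 replicate 2 and 7039 without D7 replicate 1, in place of 3215. For 3D D15 against D7 there were 8383 without D15 replicate 2 and 8278 without D7 replicate 1, in place of 18106. For 3D D25 against D15 there were 0 without D15 replicate 1, 3528 without D15 replicate 2, 434 without D25 replicate 1 and 4649 without D25 replicate 2. The balance turned without 2D D7 replicate 1 for 2D D15 against D7 (1433 opened, 1564 closed), without 3D D5 replicate 2 for 3D D5 against D3 (7853 and 7526), without either 3D D7 library for 3D D15 against D7 (4112 and 4166, 7737 and 8129) and without 3D D25 replicate 1 for 3D D25 against D15 (285 and 149). Scaling by RLE size factors changed the opened share from 75.4% to 61.2% for 2D D7 against D5, from 54.7% to 42.4% for 2D D15 against D7, from 42.8% to 32.6% for 3D D5 against D3 and from 54.8% to 41.5% for 3D D15 against D7. With only the groups compared in the fit, edgeR called 0 peaks for 3D D7 against D5, D15 against D7 and D25 against D15, with 25892, 43946 and 16010 at an unadjusted p under 0.05, while DESeq2 on all groups called 14153, 35377 and 12506. Total counts alone changed the opened share from 46.6% to 24.3% for 3D D25 against D15, and for 2D gave 11 higher and 60 lower peaks.

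**Figure D2:**
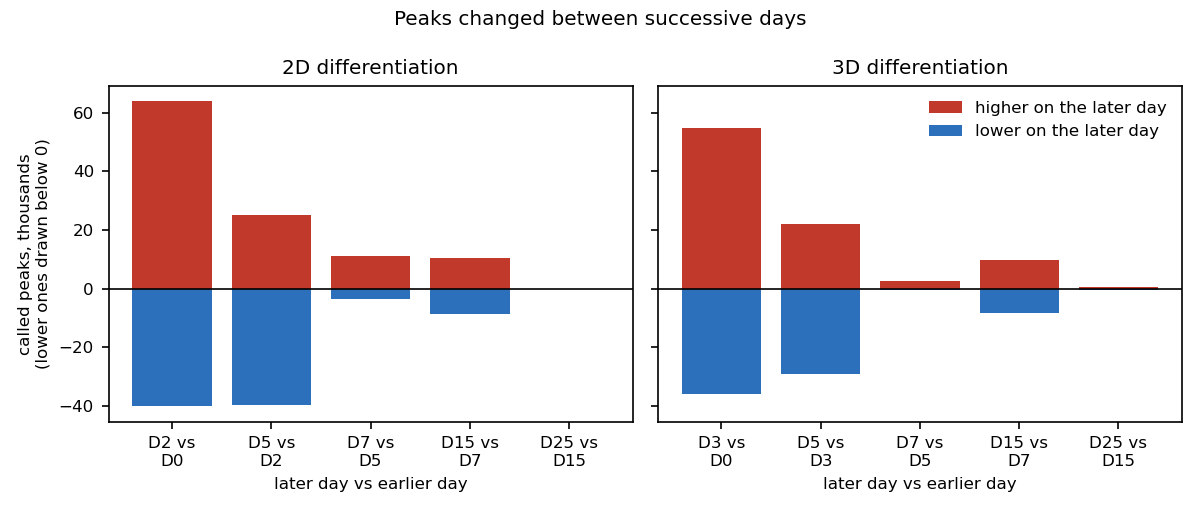
Peaks called between successive days (x axis), in units of 1000 peaks (y axis), for the 2D and the 3D format, from edgeR's quasi-likelihood test with 2 libraries per group. Red bars above 0 are peaks higher on the later day and blue bars below 0 are peaks lower on it; the first step had 63965 higher peaks in 2D and 54698 in 3D, and the last step had 0 and 450.

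Both formats opened and closed largely overlapping sets of peaks. By D25, 68197 peaks opened in both, which was 86.8% of those opened in 2D and 60.8% of those opened in 3D, against 21241 for independent lists. Peaks closed in both numbered 76981, or 81.7% and 70.1%, against 24936. Only 30 peaks opened in 2D were closed in 3D, and 162 were the reverse. At the first day sampled, 43155 peaks opened in both formats against 8436 for independent lists. Both comparisons used the same D0 libraries, so part of the overlap may come from them, and with 2 D0 libraries they could not be divided between the comparisons with 2 each. The log2 fold changes of the formats correlated at 0.796 over peaks with a covariance of 6.354, against 0.365 and 0.226 in simulated data without differences. For D25 against the first day sampled, with no common library, the correlation was 0.745 and the covariance 5.83, against 0 and 0.

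By correlation over peaks, 3D libraries lay nearest to 2D groups of a like day, with exceptions. Both 3D D3 libraries were nearest to 2D D2 (0.90 and 0.88), both D7 libraries to 2D D7 (0.88 and 0.82) and both D15 libraries to 2D D15 (0.82 and 0.82). At D5, replicate 1 was nearest to 2D D5 (0.88), and replicate 2 to 2D D7 (0.82, against 0.80 with 2D D5). At D25, replicate 1 was nearest to 2D D15 (0.79, against 0.78 with 2D D25), and replicate 2 to 2D D25 (0.77). Single pairs of 3D D25 libraries ran from 0.75 to 0.81 with 2D D25 and from 0.73 to 0.80 with 2D D15. These ranges overlap, and 2D D25 held the shallowest library. No test was made of these differences.

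Formats were compared directly at matched days. At D25, 5233 peaks were higher in 3D and 2837 lower, with median log2 fold changes of 2.99 and -2.51. At D5, 1127 were higher and 2856 lower, at D7 152 and 183, and at D15 327 and 267. The first sampled days differ in day as well as format, and there 943 peaks were higher at 3D D3 than at 2D D2 and 3913 lower. The format difference at D25 differed from that at D5 for 2276 peaks, when tested as an interaction. The signed difference of 3D minus 2D was higher at D25 than at D5 for 1288 of them and lower for 988.

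The direction and the number of these format differences were not stable. Total counts alone gave 4113 higher and 5214 lower peaks at D25, or 44.1% higher in place of 64.8%, 68.2% in place of 45.4% at D7, 35.4% in place of 19.4% for the first sampled days, and 36.4% in place of 56.6% for the interaction. At D25 there were 6 calls without 2D D25 replicate 1, 1451 without 2D D25 replicate 2, 17347 without 3D D25 replicate 1 and 2454 without 3D D25 replicate 2. At D5 there were 12825 without 3D D5 replicate 1 and 0 without any other library. At D7 there were 12232 without 3D D7 replicate 1, 2 without 2D D7 replicate 1 and 0 without either of the others. At D15 there were 1621 without 3D D15 replicate 1, 3286 without 3D D15 replicate 2 and 0 without either 2D D15 library. For 3D D3 against 2D D2 there were 614 and 1 without 2D D2 replicate 1 or 2, and 1845 and 2 without 3D D3 replicate 1 or 2. For the interaction there were 0 and 398 without 2D D25 replicate 1 or 2, 4 and 7 without 2D D5 replicate 1 or 2, 7761 and 1495 without 3D D25 replicate 1 or 2, and 5752 and 1 without 3D D5 replicate 1 or 2. Higher and lower calls changed order without 2D D25 replicate 1 (1 and 5) or 2 (383 and 1068) at D25, without 3D D7 replicate 1 (7131 and 5101) at D7 and without 3D D3 replicate 1 (1043 and 802) for the first sampled days. For the interaction they did so without 2D D25 replicate 2 (110 and 288), 3D D25 replicate 2 (722 and 773) or 3D D5 replicate 2 (0 and 1). Fitted on the 4 libraries of the comparison alone, edgeR's test called 0 peaks at D7, D15 and D25, with 41540, 51675 and 25183 at an unadjusted p under 0.05, and 6520 at D5. DESeq2 on all groups called 10830, 12535 and 19904 at D7, D15 and D25.

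Nuclei grouped into clusters that followed day and format. Cluster 4 held 98.1 ± 0.548% of D0 nuclei (SD, n = 2). At 2D D2, clusters 7 and 10 held 53.8 ± 1.91% and 41.7 ± 1.52%, and at 2D D5, clusters 5 and 6 held 54.4 ± 3.37% and 35.9 ± 3.17%. Cluster 3 held 70.2 ± 17.8% of 2D D7 nuclei. Cluster 1 held 81.5 ± 3.5% at 2D D15, 76.9 ± 10.3% at 2D D25 and 27.3 ± 8.94% at 3D D15, but 0.546 ± 0.568% at 3D D25. There, cluster 8 held 65.4 ± 29.8%, against 1.22 ± 0.454% at 2D D25.

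**Figure D3:**
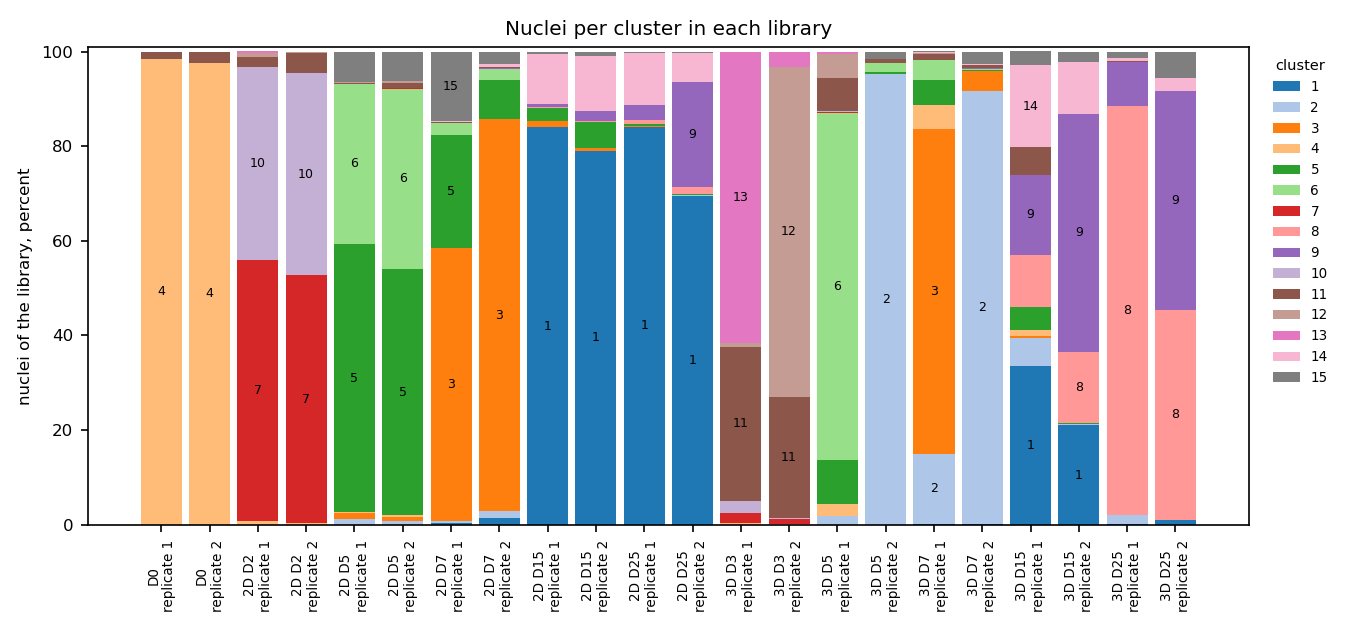
Percent of the nuclei of each library (y axis) in each of 15 clusters (colours, with numbers in the larger segments) for the 22 libraries (x axis). Replicates have like shares at D0, 2D D2, 2D D5 and 2D D15, while cluster 2 holds 1.8% and 95.2% of the 3D D5 libraries.

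Replicates differed more in 3D. Cluster 2 held 1.8% of 3D D5 replicate 1 (95% Wilson interval 1.51 to 2.05) and 95.2% of replicate 2 (94.8 to 95.6), and at 3D D7 14.7% (13.9 to 15.4) and 91.6% (91.1 to 92.1). Cluster 6 held 73.4% of 3D D5 replicate 1 (72.5 to 74.3), and cluster 3 held 68.7% of 3D D7 replicate 1 (67.7 to 69.7). At 3D D3, cluster 13 was 32.3 ± 41.3% and cluster 12 was 35.3 ± 48.8%. By library, cluster 13 held 61.5% of replicate 1 and 3.1% of replicate 2, and cluster 12 held 0.835% and 69.8%. These libraries had barcodes of 20 and 22 bases, as did the D0 libraries, of which cluster 4 held 98.4% and 97.7%. The 2D libraries also differed late, with cluster 9 at 12.7 ± 13.4% of 2D D25.

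In edgeR's quasi-likelihood test of nuclei per cluster with Benjamini-Hochberg adjustment over clusters, cluster 1 was lower in 3D at D25 (log2 ratio -7.13, SE 1.79, adjusted p = 0.021) and cluster 8 higher (5.75, SE 1.44, adjusted p = 0.021), in both 3D libraries against both 2D libraries. Cluster 8 was also higher in 3D at D15 (6.13, SE 1.47, adjusted p = 0.032). In simulated data for D25 this test also called 7.54% of unchanged clusters, so any of these calls may be false. At D5 and D7 no cluster was called by edgeR, and no cluster of D5 or D7 had an unadjusted p under 0.05, with no other tool run. Clusters were built on the tested peaks and follow the libraries, so they are not separate evidence of a format difference. With a lower or a higher resolution, or a minimum of 2000 counts per nucleus, 0 clusters were called at D15 and 1 at D25. The call at D15 also ended without any 1 of the 4 D15 libraries, and both calls at D25 ended without 2D D25 replicate 1, 2D D25 replicate 2 or 3D D25 replicate 1.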

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

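Some tests were chosen only after the results were seen. They were the weighing of exchanged labels and of the peaks of cluster 9 at D5 and D7, and the fit without cluster 9. So were the tests of depth per nucleus and of single counts, which were built on clusters and library differences already seen. The tests between formats, the thinned fit and the fits with a library left out were set down before.

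The change since D0 differed between the formats for 3983 peaks at D5, 335 at D7, 594 at D15 and 8070 at D25. D0 is common to both formats and cancels, so these are the same calls as 3D against 2D on each day, not a second result. The format difference itself differed between D25 and D5 for 2276 peaks. Each of these counts moved by over 1.5 times when a library was left out. At D5 it was 12825 without 3D D5 replicate 1 and 0 without any other library, at D7 12232 without 3D D7 replicate 1, 2 without 2D D7 replicate 1 and 0 without the others, and at D15 1621 and 3286 without 3D D15 replicate 1 or 2 and 0 without either 2D D15 library. At D25 it was 6 and 1451 without 2D D25 replicate 1 or 2 and 17347 and 2454 without 3D D25 replicate 1 or 2. For the interaction it was 0 and 398 without 2D D25 replicate 1 or 2, 4 and 7 without 2D D5 replicate 1 or 2, 7761 and 1495 without 3D D25 replicate 1 or 2, and 5752 and 1 without 3D D5 replicate 1 or 2.

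For 3D against 2D at D25, unequal shares of cluster 9 (9.3% and 46.2% in the 3D libraries, 3.2% and 22.1% in the 2D libraries) were tested as the whole cause. Without its nuclei 8124 peaks were called in place of 8070. Of the 8070, only 4131 were among them, and these argue against it as the whole cause. The total itself decides nothing, since the shares also differed between replicates and leaving the nuclei out can change the spread. Cluster 9 stays open as part of the cause. With every library thinned to the smallest total 2717 peaks were called, between the bounds set for and against unequal depth, so depth stays open as part of the cause. The count was 6 without 2D D25 replicate 1, 1451 without 2D D25 replicate 2, 17347 without 3D D25 replicate 1 and 2454 without 3D D25 replicate 2. A difference between the formats, which the design names, remains among the open explanations.

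The 3D replicates stood apart at D5 and D7, where cluster 2 held 1.8% and 14.7% of replicate 1 but 95.2% and 91.6% of replicate 2. Depth per nucleus as the cause is argued against, since among nuclei of 2000 to 4000 counts the shares still differed by at least 75.7 percentage points, and so is the low share of single counts in 3D D5 replicate 2, whose difference from replicate 1 correlated at 0.05 over peaks with that between the 2D D5 libraries. An exchange of the D5 and D7 labels in 3D is argued against too, since 0 of the 3D D7 libraries were nearest to 2D D5. That test says nothing of 3D D5 replicate 2, which was nearest to 2D D7. Its shares over clusters overlapped by 94.4% with 3D D7 replicate 2 and by 5.1% with 3D D5 replicate 1. Over 7392 peaks higher in cluster 9 than in cluster 1 among late 2D nuclei, replicate 2 of 3D D7 lay above replicate 1 by a median log2 of 1.51 (quartiles 0.73 to 2.29), while 4598 peaks lower in cluster 9 had a median of -0.85, so openness of cluster 9 peaks may be part of the D7 difference, although the lower peaks also differed between the 2D D7 libraries (medians of -0.16 and 0.89). At D5 the medians were 0.41 and 0.23, both above 0, which decides nothing, and no biological explanation was tested, as the labels give no difference between replicates.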

How the results depend on the processing

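The fits with fragments, a barcode term, scaling per block of peaks, and without cluster 9 or clusters 9 and 15 were tests chosen only after the results were seen; the others were planned. Of 162 planned peak counts other than those with a library left out, 94 lay within 1.5 times the reported count, as did 35 of 62 added ones, and 17 of 76 with a library left out. No cluster was called at D5 or D7 in any setting, so these say nothing of stability. The 4 single peaks were picked as the largest changes of 2D D25 against D0, so their values say little of other peaks. All 84 values of the 4 single peaks kept their direction and call, with a highest adjusted p of 0.0029 (edgeR's quasi-likelihood test or DESeq2, with Benjamini-Hochberg adjustment). Without 3D D25 replicate 2, 12 calls of 3D D25 against D0 turned direction. The share of 2D D2 openings also open at D25 ranged from 15.1% to 22.1%, the share of closures from 51.7% to 79.9%, those in 3D from 27.3% to 37.2% and 68.3% to 83.9%, and the shares of 2D changes by D25 that 3D had too from 73.7% to 90.2% and 69.7% to 89.1%. Gene loci, gene lists, motifs and nuclei named by markers were planned but not run. Thinning leaves fewer counts and a left-out library fewer samples, where the lone library is assumed to vary like the other groups, but counts moved both ways under each. Thinned, 2D D25 against D15 went from 3 to 69, and without 3D D25 replicate 1, 3D against 2D at D25 went from 8070 to 17347. For all of these moves the cause was not tested.

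Counts that moved by over 1.5 times are given by setting. Thinned to the smallest total, 3D D25 against D0 had 133527 peaks, the 2D steps in order 59222, 32853, 6849, 9451 and 69, the 3D steps 50813, 28311, 1629, 6314 and 440, 3D against 2D at D5, D7, D15 and D25 2234, 199, 319 and 2717, 3D D3 against 2D D2 1365 and the interaction 944. DESeq2 called 32139, 36073 and 1767 in the 2D steps from D5 on, 14153, 35377 and 12506 in those of 3D, 16566, 10830, 12535 and 19904 between formats, 14851 for the first days and 13517 for the interaction. With only the groups compared, the 2D steps had 170545, 132676, 53437, 43956 and 8417, the last 3 steps in 3D 0, the formats 6520 at D5 and 0 at D7, D15 and D25, the first days 27519 and the interaction 67. RLE gave 7 for 2D D25 against D15, 1597 for 3D D25 against D15 and 176 at D7. Total counts gave 71 and 3923 for D25 against D15 in 2D and 3D and, between formats, 1504 at D5, 198 at D7 and 292 at D15, and 2934 for the first days. Scaling per block gave 62, 3201, 1525, 208, 289 and 2680 for the same. Fragments gave 22039 for 2D D7 against D5, 16 and 2125 for D25 against D15 in 2D and 3D, 4823 for 3D D7 against D5, 10935, 5550 and 1757 at D5, D7 and D15, and 11816 for the first days. Nuclei counted once per peak gave 23013, 28, 2263, 4982, 11483, 5527, 2809 and 12715 for the same. A barcode term gave 31406 for 3D D5 against D3, 494 for 3D D25 against D15, 2106, 0 and 41 at D5, D7 and D15, 2174 for the first days and 1382 for the interaction. Without cluster 9 there were 37 and 4647 for D25 against D15 and 104 at D15, and without clusters 9 and 15 there were 55, 5941 and 185. Without the nuclei with the most counts there were 15 for 2D D25 against D15 and 1085 at D15. At 2000 counts per nucleus, a lower or a higher resolution, 0 clusters were called at D15 and 1 at D25.

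With a library left out, D25 against D0 ranged from 116873 to 140936 in 2D and 173666 to 205409 in 3D. The 2D steps ranged from 55733 to 66648, 23120 to 35016, 567 to 10628, 2997 to 10300 and 0 to 2. The 3D steps ranged from 46008 to 61338, 15379 to 58162, 11 to 7039, 8278 to 15866 and 0 to 4649. Between formats the ranges were 0 to 12825 at D5, 0 to 12232 at D7, 0 to 3286 at D15, 6 to 17347 at D25, 1 to 1845 for the first days, 0 to 7761 for the interaction, 0 clusters at D15 and 0 to 2 at D25.

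The replicate numbers were checked for pairing. Deviations of libraries with the same number correlated at a median of 0.02 over 55 pairs of groups (-0.15 to 0.34), with 11 over 0.1. Among 3D D5, D7, D15 and D25 the 6 pairs lay at 0.04 to 0.34 with a median of 0.27, 5 of them over 0.1, while none of the 10 pairs of 2D groups was. Since not every pair passed 0.1 and no label ties the numbers to a culture or day, the numbers were not taken as pairs, and a link among the later 3D libraries stays open. The replicate block gave 70 and 1478 calls for D25 against D15 in 2D and 3D, 8012, 2259 and 3437 between formats at D5, D7 and D15, 3558 for the interaction and 0 clusters at D15, and moved no other count of calls by over 1.5 times.

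The largest library total was 11.03 times the smallest. In simulated data with 200 changed peaks, 5.97% of 4-fold and 47.0% of 8-fold changes of 2D D25 against D15 were recovered. For the deeper 3D D25 against D0 these shares were 10.4% and 47.0%. The real data gave 221936 calls for 3D D25 against D0, so its adjusted threshold was less strict. The simulated shares therefore do not carry over to it. For 2D D25 against D15, with 3 calls in the real data, most simulated 4-fold changes were not recovered.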

Other observations

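The test of late steps between formats, the fit with each block scaled on its own and the correlations of replicate differences below were chosen only after the results were seen; the thinned fit was set down before.

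Blocks of peaks took unlike parts in the course. In block 19, 40.5% of tested peaks opened and 8.55% closed by D25 in 2D, and 45.0% and 12.5% in 3D. Its share of all counts was 2.26 ± 0.144% at D0 (SD, n = 2), 4.70 ± 0.0195% at 2D D15, 4.75 ± 0.201% at 2D D25, 4.67 ± 0.0313% at 3D D15 and 3.83 ± 0.274% at 3D D25. In block 13, 15% opened and 28.2% closed in 2D and 23.6% and 31.8% in 3D. With each block scaled on its own total, without TMM, 60375 peaks opened and 113450 closed in 2D by D25. Total counts as the only scaling gave nearly the same, 61592 and 115780, so scaling by block itself moved these counts little. No test was made of the blocks.

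A small part of 3D replicate 1 nuclei lay in cluster 4, which held 98.1 ± 0.548% of D0. The shares were 2.4% at D5 (95% Wilson interval 2.15 to 2.78), 5.1% at D7 (4.60 to 5.54) and 1.2% at D15 (0.983 to 1.52), against 0.029% (0.00997 to 0.0862), 0.028% (0.0095 to 0.0821) and 0 of 7856 nuclei in replicate 2. The differences of replicate 2 from replicate 1 correlated over peaks at 0.34 between 3D D5 and D7, 0.27 between D7 and D15, 0.27 between D7 and D25 and 0.32 between D15 and D25, but at 0.04 between D5 and D25. Cluster 14 held 11 ± 0.723% at 2D D15 and 8.54 ± 3.47% at 2D D25, 14.1 ± 4.45% at 3D D15 and 1.78 ± 1.63% at 3D D25.

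The step from D15 to D25 gave 966 calls in 3D and 3 in 2D, a contrast that low depth of the 2D D25 libraries could produce. With every library thinned to the smallest total, 440 peaks were called in 3D and 69 in 2D, so the contrast shrank, and the 3D count met neither bound set beforehand. A test of the difference between the steps called 0 peaks with edgeR, with 37228 at an unadjusted p under 0.05. Of the 966 peaks, 86% moved the same way in 2D, with a median log2 fold change of 0.80 in the direction of 3D, against a median size of 2.79 in 3D, and these peaks were picked for their change in 3D (over all 414729 peaks the changes of the formats correlated at 0.14). The 966 became 0 without 3D D15 replicate 1, 3528 without D15 replicate 2, 434 without D25 replicate 1 and 4649 without D25 replicate 2, and the 3 became 0 without either 2D D25 library, so depth stays open.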
